A study of Mus musculus with 8 samples.

How the data were processed

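Total RNA of adult mouse testis was extracted with TRIzol and treated with DNase, and libraries were made with the TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name Trimmomatic, Subread and featureCounts and the mouse genome build GRCm39 (mm39). Their versions, the annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here, so overlapping and antisense genes and close gene copies are uncertain. The data were a matrix of 24988 Ensembl genes by 8 libraries. The authors deposited it as a per-library scaled signal, named CPM (read counts scaled by library size) in the file, with columns named control and kpn and numbered 1 to 4. These were matched to the titles of the wild-type and the knockout samples by their numbers, taking control to mean wild type. No other column of sample values was present.

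Each column of CPM summed to between 990244 and 1025490, so the authors had scaled with library sizes that differ from the column totals. In every column all values were whole multiples, within 0.01, of the smallest value above 0 (100% of values), and dividing by it gave back whole reads, 31133443 to 37797812 per library. The lowest total of a listed gene over the 8 libraries was 30 reads, and every row named a gene. A floor of 3 reads per library corresponds to between 0.0786 and 0.0968 CPM, for counting error only. The plan had taken the table to be plain CPM, and its test on the log scale was kept, since it fits the scaled values.

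The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(CPM + 0.5), for 22027 genes with a mean of at least 0.5 CPM over all 8 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate was used. Gene lists were tested with camera of limma (preset correlation 0.01 between genes, at least 3 measured members, adjusted over 38 lists), beside camera with an estimated correlation and the directional p of fry, which asks whether a list's genes move one way without comparing them with other genes. Of 39 lists, that of ribosomal RNA related loci had 1 measured member, which was not called, and was not tested as a set. Kpna2 was also compared by an exact two-sided permutation test of CPM. Genes were named by a rule: the importin alpha genes, the 8 largest rises and 8 largest falls and the 4 smallest p in each direction among called genes with a mean of at least 5 CPM, no overlap between groups and a symbol that is not a clone or predicted-gene name, and up to 3 members of smallest p of each described list with the first member that goes the other way. Lists, rule, main tests and most alternatives were fixed before the data were examined.

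Symbols were found for 24890 identifiers. Positions, gene types, GC content and lengths came from GENCODE mouse release M21 on GRCm38, which is another build than the authors used, so coordinates are those of GRCm38 and were not converted. Replicates were compared before they were averaged: the chi-square of read counts per degree of freedom was 4.99 to 12.9 for pairs within a group, so no pair agreed within sampling noise.

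On simulated counts for the 22027 genes of this comparison, 200 changes were planted, and a list of further genes was shifted lower. Of the 200, the main test recovered 53.7% of 1.5-fold, 88.1% of 2-fold and 100% of 4-fold changes. Of all its calls, those in the shifted list included, 9.45% were unchanged genes. Far fewer genes changed in the simulation than were called in the data, so these rates do not carry over directly. The alternatives were median ratio scaling, quantile normalization, pseudocounts of 0.1 and 2 CPM, no filter and a filter at 2 CPM, no variance trend, library weights, the replicate number as a block, each library left out in turn, and edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 (Wald test) on the recovered reads with the authors' scaling. The edgeR test called 3694 genes, of which 3630 were also called by limma, all in the same direction.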

Results

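RNA from adult mouse testis was sequenced in 8 libraries, of which 4 were labelled Kpna2 knockout and 4 wild type. Kpna2 encodes an importin alpha, an adaptor that carries proteins with a nuclear localization signal into the nucleus. The comparison asked which genes are expressed differently in the testis of Kpna2 knockout mice, in a study of male infertility and of the nuclear import of testis transcription factors. The libraries held between 31133443 and 37797812 reads assigned to 24988 genes. Values are CPM (read counts scaled by library size) as mean ± SD with n = 4 libraries per group. The labels do not say whether the 4 libraries of a group came from 4 animals, so that p-values measure only the spread between these libraries. Log2 fold changes are on the scale of log2(CPM + 0.5), which understates the change of low genes, and are given as libraries labelled knockout minus libraries labelled wild type. Genes said to rise or fall, or not to, are those called or not called by limma unless another tool is named.

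Kpna2 itself (ENSMUSG00000018362; chromosome 11, 106988629 to 106999541 in GRCm38) was not lower in the libraries labelled knockout. It stood at 13.9 ± 1.11 CPM in the libraries labelled wild type and at 19.2 ± 2.76 CPM in those labelled knockout, a mean 38.1% higher. The 4 values were 13.97, 15.1, 14.04 and 12.4 CPM under the wild-type label and 15.3, 20.2, 19.4 and 21.7 CPM under the knockout label, from 465 to 746 reads per library. The log2 fold change was 0.44 with an SE of 0.10 and a limma adjusted p of 0.0079, and all 4 libraries labelled knockout lay above all 4 labelled wild type. The exact two-sided permutation test of the 4 against 4 values gave p = 0.029, the smallest p that 70 assignments allow. The target gene therefore goes against the label, and every direction below is that of the libraries labelled knockout. Values per gene do not show which exons the reads covered, so a transcript that lacks a deleted part would still be counted. The treatment of reads that match several places is not given either, so reads from any copies of Kpna2 may add to its values. The other importin alpha genes did not pass the test: Kpna1 stood at 55.3 ± 2.29 and 49.8 ± 3.31 CPM, Kpna3 at 31.1 ± 2.15 and 28.7 ± 1.80, Kpna4 at 175 ± 11.1 and 180 ± 5.76, Kpna6 at 325 ± 8.98 and 330 ± 12.1, and Kpna7 at 3.81 ± 0.609 and 3.87 ± 0.711 in the libraries labelled wild type and knockout. Their limma adjusted p lay between 0.099 (Kpna1) and 0.96 (Kpna7).

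**Figure D1:**
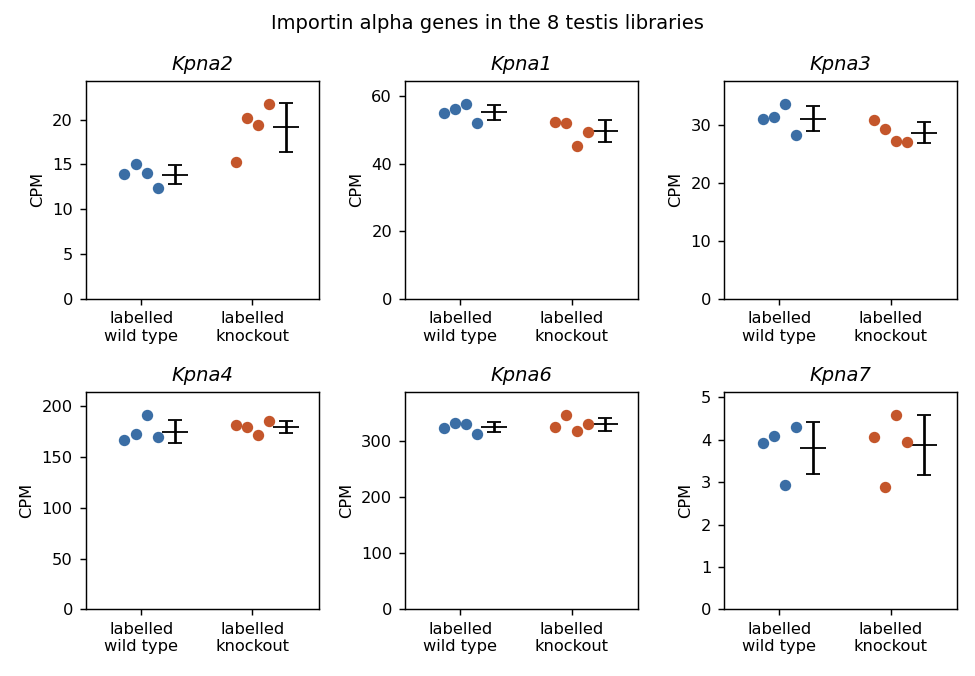
CPM of 6 importin alpha genes in each of the 8 libraries (points), with the mean and SD of each group of 4 (bars), by the group named in the labels. The 4 Kpna2 values under the knockout label lie between 15.3 and 21.7 CPM, above the 4 under the wild-type label, and for the other 5 genes the values of the groups overlap.

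Of 30 measured importins, exportins and genes of the Ran cycle, which drives nuclear transport, Kpna2 alone was called by limma and by edgeR, and DESeq2 called 2, both higher. Ipo7, an import receptor, stood at 42.4 ± 2.36 and 47.8 ± 3.31 CPM, and Rcc1, the exchange factor of Ran, at 286 ± 8.35 and 316 ± 15.5 CPM, without passing the test (limma adjusted p = 0.089 and 0.055). Among 28 nucleoporins, the building blocks of the nuclear pore, Nup35 (1.34-fold, from 18.1 ± 0.572 to 24.3 ± 2.20 CPM) and Nup43 rose and Rae1 fell, of which Nup43 was not called in 4 of 19 alternatives. Rcc1 passed in 5 of them and Ipo7 without knockout replicate 3, where it stood at 42.9 CPM against 48.8 to 49.9 CPM in the other libraries of its group. Neither list shifted as a set (camera adjusted p = 0.66 and 0.77).

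At an adjusted p under 0.05, limma called 3731 of 22027 tested genes (16.9%), 1898 of them higher and 1833 lower in the libraries labelled knockout. The change of called genes was mostly small, with a median size of 0.48 on the log2 scale, and 398 genes changed by at least 1 log2 unit (159 higher, 239 lower). The values of the 4 against 4 libraries did not overlap for 4593 genes, 20.9% of those tested against 2.86% by chance. On the first principal component, with 52.0% of the variance, the 2 groups stood apart. Spearman correlations of log2 values across genes, which are not independent, were 0.992 to 0.994 within the libraries labelled wild type, 0.989 to 0.992 within those labelled knockout and 0.979 to 0.983 between them. Changes of at least 1 log2 unit were found for 1.27% of 15881 protein-coding genes, 2.94% of 3610 long non-coding RNA genes and 4.25% of 1953 pseudogenes. The count of large changes depends on the pseudocount: it was 645 with 0.1 CPM and 149 with 2 CPM.

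The largest rise among the genes named by the rule was that of Klrb1, a lectin-like receptor gene of lymphoid cells (chromosome 6, 128705836 to 128723059 in GRCm38). It had no read in any of the 4 libraries labelled wild type and 21.2 ± 0.799 CPM in those labelled knockout, at least 224-fold higher when the empty libraries are set at a floor of 3 reads each (limma adjusted p = 6.6e-13). Hsd3b1, a dehydrogenase of steroid hormone synthesis, rose 3.75-fold from 22.4 ± 1.84 to 83.9 ± 14.2 CPM, and Fmn1, an actin-assembling formin, 2.93-fold from 36.7 ± 1.56 to 108 ± 7.02 CPM. Syt3, a synaptotagmin of vesicle traffic, rose 4.83-fold, the secretoglobin pseudogene Scgb2b23-ps 3.51-fold, Fxyd5, which modulates the sodium pump, 3.09-fold, Sardh, sarcosine dehydrogenase, 3.02-fold, and Pop4, a subunit of ribonuclease P, 2.68-fold. Camk2n1, an inhibitor of CaM kinase, was among the smallest p of the risers with 68.7 ± 3.52 against 160 ± 18.4 CPM (limma adjusted p = 1.0e-07).

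On the scale of log2(CPM + 0.5) the largest fall among the genes named by the rule was that of Dynlt1b, a dynein light chain (chromosome 17, 6430112 to 6436296 in GRCm38), from 176 ± 55.7 to 5.71 ± 8.98 CPM, a 30.8-fold lower mean (limma adjusted p = 2.1e-05). Its value under the knockout label was 19.2 CPM in replicate 1 and at most 1.57 CPM in the other 3. The neighbouring Tmem181b-ps fell from 27.3 ± 4.65 to 2.45 ± 3.08 CPM. Zfp990, a zinc finger gene, fell 48.3-fold from 26.8 ± 0.767 to 0.555 ± 0.128 CPM, and Hist1h2al, a histone gene copy that the annotation lists as a pseudogene, 25.4-fold from 37.7 ± 2.93 to 1.48 ± 0.156 CPM. Ttc22 fell 32.6-fold, the complement protease gene C1rb 14.5-fold and the kallikrein Klk1b21 9.53-fold. Lpo, lactoperoxidase, had 1513 reads under the wild-type label and 10 under the knockout label. Ndufaf3, an assembly factor of mitochondrial complex I, fell 2.89-fold from the high level of 754 ± 33.8 to 261 ± 22.2 CPM (limma adjusted p = 1.9e-09), and Smim10l1, a small membrane protein gene, 4.21-fold. Dynlt1b, Tmem181b-ps, Hist1h2al, Klk1b21, C1rb, Klrb1, Hsd3b1, Zfp990 and Scgb2b23-ps belong to families with close copies. Their values are uncertain, because the treatment of reads that match several copies is not given in the sources used here.

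**Figure D2:**
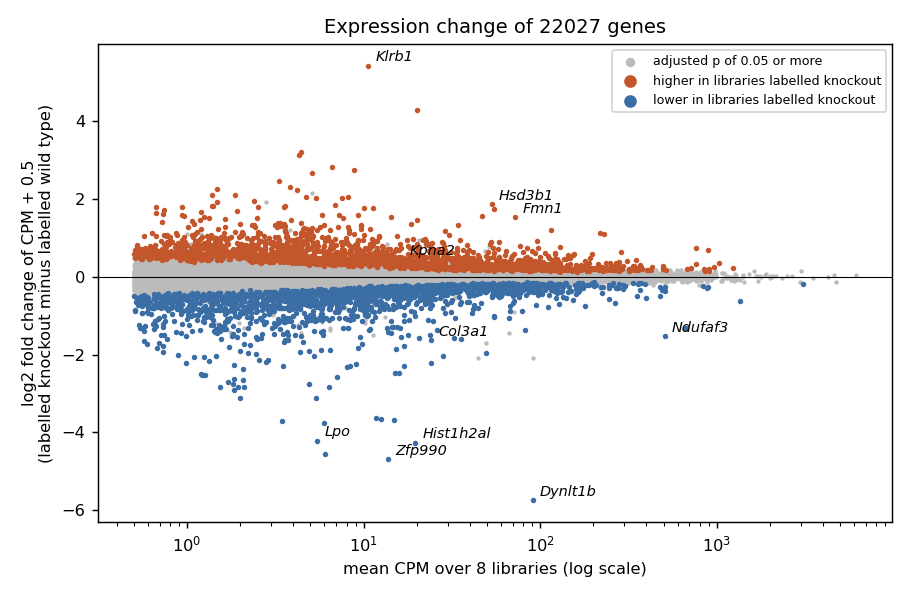
Log2 fold change of CPM + 0.5 (libraries labelled knockout minus libraries labelled wild type) against mean CPM (log axis) for 22027 genes. Coloured points are the 1898 higher and 1833 lower genes at an adjusted p under 0.05, and Klrb1 and Dynlt1b lie at the 2 extremes.

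Genes of the extracellular matrix fell together. Of 25 members, 20 fell and none rose (22 fell adjusted over the list alone), with a median log2 fold change of -0.59. The fibrillar collagen genes Col3a1 and Col1a2 fell from 36.3 ± 5.52 to 11.7 ± 3.48 CPM and from 37.3 ± 6.23 to 14.8 ± 4.71 CPM, that is 3.10-fold and 2.53-fold, and Eln, elastin, from 7.32 ± 1.18 to 3.13 ± 0.807 CPM. The list's mean relative to the wild-type label was -0.92 in knockout replicate 4 and -0.57 to -0.52 in the other 3, against -0.10 to 0.09 in the libraries labelled wild type. The list's camera adjusted p was 4.8e-11 with the preset correlation, and its adjusted p = 0.89 with an estimated correlation. Of 12 markers of peritubular myoid cells, the contractile cells around the tubules, 5 fell and none rose. Acta2, smooth muscle actin, went from 41.3 ± 4.77 to 28.5 ± 3.80 CPM, Myh11, smooth muscle myosin, from 28.8 ± 4.13 to 18.3 ± 3.37 CPM and Actg2 from 296 ± 19.5 to 246 ± 3.87 CPM, while Flna stood at 56.1 ± 5.05 and 58.9 ± 4.66 CPM (limma adjusted p = 0.56). That list's camera adjusted p was 0.014, and its adjusted p = 0.89 with an estimated correlation. Its mean relative to the wild-type label was -0.19 in wild-type replicate 3 and 0.04 to 0.08 in the other 3 of that group, against -0.22 and -0.21 in knockout replicates 2 and 3 and -0.27 and -0.45 in replicates 1 and 4.

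Leydig cell genes, which serve androgen synthesis, went both ways. Star, which brings cholesterol into mitochondria for steroid synthesis, fell 2.45-fold from 116 ± 27.9 to 47.4 ± 20.9 CPM, and Lhcgr, the receptor of luteinizing hormone, 1.81-fold from 12.6 ± 1.72 to 6.97 ± 0.887 CPM, whereas Hsd3b1 rose. In all, 7 of 21 members fell and 1 rose (8 and 3 adjusted over the list alone), and the list did not pass the set test (camera adjusted p = 0.059). Relative to the mean under the wild-type label, the list's mean log2 value was -0.32 and -0.29 in knockout replicates 1 and 4. In knockout replicates 2 and 3 it was -0.03 and -0.0022, inside the range of -0.07 to 0.11 under the wild-type label, and the list passed when either of these 2 replicates was left out. Of 24 genes of cholesterol synthesis and transport, 7 fell and none rose (8 fell adjusted over the list alone). They included Stard4, from 12.4 ± 1.48 to 6.79 ± 1.32 CPM, Dhcr7, which makes cholesterol in the last step of its pathway, from 20.9 ± 2.86 to 14.2 ± 2.70 CPM, and Msmo1 from 18.9 ± 1.35 to 13.3 ± 2.58 CPM. The median was -0.18, with a camera adjusted p of 0.014 and an adjusted p = 0.89 with an estimated correlation. The list's mean was again lowest in knockout replicates 1 and 4 (-0.30 and -0.36, against -0.13 and -0.11 in replicates 2 and 3 and -0.12 to 0.16 under the wild-type label), and it did not pass without wild-type replicate 4 or without knockout replicate 1. Adipocyte markers were lowest in these same libraries, with list means of -0.64 and -0.74 in knockout replicates 1 and 4, -0.20 and 0.12 in replicates 2 and 3, and -0.24 to 0.42 under the wild-type label.

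Among 30 Sertoli cell markers, 6 fell and 1 rose. Sox9, the transcription factor of Sertoli cell identity, fell from 17.7 ± 1.05 to 11.9 ± 1.85 CPM and Defb36 from 31.9 ± 1.49 to 24.0 ± 1.63 CPM, whereas Ptgds, prostaglandin D synthase, rose 2.09-fold from 149 ± 47.2 to 312 ± 65.2 CPM. The list's median was -0.12, with a camera adjusted p of 0.036 and an adjusted p = 0.89 with an estimated correlation. Its mean was -0.11 and -0.18 in knockout replicates 1 and 4, but -0.02 and -0.04 in replicates 2 and 3, inside the range of -0.09 to 0.06 under the wild-type label. It did not pass without wild-type replicate 1, 3 or 4 or without knockout replicate 1 or 4. Of 15 endothelial markers, Tek and Vwf fell and Sox17 rose (3 and 2 adjusted over the list alone), and of 18 macrophage markers 1 fell and 1 rose (none and 1 adjusted over the list alone). Neither passed the set test (camera adjusted p = 0.87 and 0.62).

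Mitochondrial transcripts were also lower. Of 15, 7 fell and none rose (9 fell adjusted over the list alone), among them mt-Nd1 from 969 ± 54.8 to 793 ± 83.5 CPM, mt-Nd4 from 549 ± 25.9 to 434 ± 58.9 CPM and the ribosomal RNA mt-Rnr1 from 73.2 ± 4.98 to 57.0 ± 5.76 CPM. The other ribosomal RNA, mt-Rnr2, stood at 76.5 ± 3.37 and 78.0 ± 7.63 CPM. The camera adjusted p was 0.014, with an adjusted p = 0.89 with an estimated correlation. The list's mean in knockout replicate 2 (-0.01) lay inside the range of -0.09 to 0.12 under the wild-type label, and in the other 3 it was -0.35 to -0.19. The list did not pass without knockout replicate 1. Mitochondrial genes took 0.702% to 0.787% of the CPM in the libraries labelled wild type and 0.573% to 0.699% in those labelled knockout. These 5 lists, all lower, were the ones past the threshold among 38 tested, and none of the 38 passed with an estimated correlation. Of these 5 lists the extracellular matrix list alone passed fry, while peritubular myoid cells, cholesterol synthesis, Sertoli cells and mitochondrial transcripts did not (fry adjusted p = 0.11, 0.15, 0.15 and 0.16). The count was 3 without wild-type replicate 4 and 2 without knockout replicate 1. Of the 35 ways to split the 8 libraries into 4 and 4, 20 gave 5 or more lists, the real split included.

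**Figure D3:**
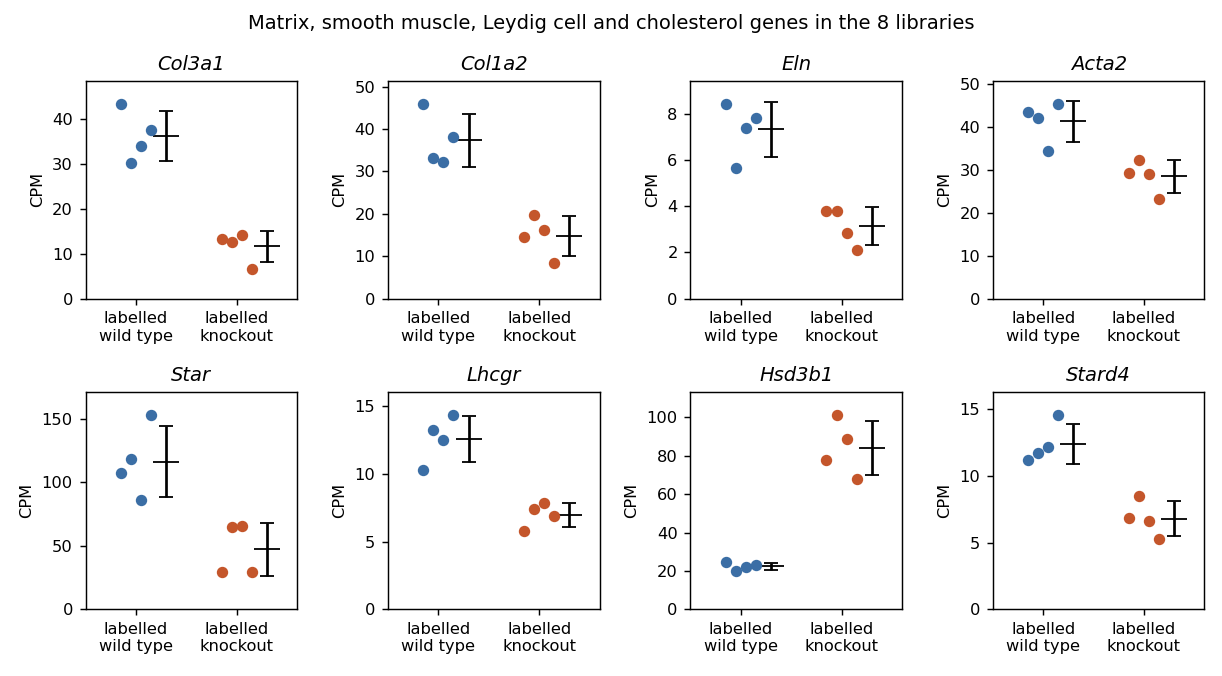
CPM of 8 genes of the matrix, smooth muscle, Leydig cells and cholesterol metabolism in each of the 8 libraries (points), with the mean and SD of each group of 4 (bars), by the group named in the labels. Col3a1, Col1a2, Eln, Acta2, Star, Lhcgr and Stard4 are lower and Hsd3b1 is higher under the knockout label, with no overlap between the groups.

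Genes of spermatids, pachytene spermatocytes and the piRNA pathway and testis transcription factors had few calls. None of the 29 genes of elongating spermatids and sperm chromatin was called by limma, nor by edgeR, and 4 had an unadjusted p under 0.05, while DESeq2 called 1 higher (Akap14) and 1 lower (Car2). Akap14, an anchoring protein of the flagellum, stood at 13.7 ± 0.940 and 16.3 ± 1.46 CPM, Car2 at 166 ± 7.11 and 149.5 ± 8.603 CPM and Spem1, a gene of spermatid maturation, at 538 ± 27.9 and 478 ± 46.2 CPM. They passed in 3, 2 and 2 of 19 alternatives, quantile normalization being among these for each. Of 16 testis histone variants none was called by limma, edgeR or DESeq2, and 1 had an unadjusted p under 0.05. In round spermatids 1 of 25 genes, in the acrosome 1 of 25, in pachytene spermatocytes 1 of 17 and in the piRNA pathway and germ granules 1 of 20 rose, with no fall in these 4 lists. Of 35 testis transcription factors and cofactors, 2 rose and none fell: Klf4 from 152 ± 5.25 to 189 ± 13.0 CPM and Nr6a1, the germ cell nuclear factor, from 206 ± 6.10 to 235 ± 11.01 CPM. Dmrtb1, which acts at the entry into meiosis, stood at 555 ± 48.1 and 631 ± 34.8 CPM (limma adjusted p = 0.058) and passed in 5 of 19 alternatives, and Ovol1 at 11.2 ± 0.668 and 10.04 ± 0.502 CPM (limma adjusted p = 0.23).

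Earlier germ cells and dividing cells showed changes in both directions. Since 16.9% of all tested genes were called, a few calls in a list, here and below, do not set it apart. In the list of meiotic recombination and the synaptonemal complex, 3 of 32 genes rose and 4 fell. Mei1 rose from 9.03 ± 0.662 to 14.2 ± 0.783 CPM and the helicase gene Hfm1 from 42.6 ± 1.26 to 60.2 ± 5.93 CPM, whereas Meiob fell from 20.72 ± 2.15 to 15.04 ± 0.440 CPM. Of 16 markers of undifferentiated spermatogonia, Tspan8 rose and 2 fell, Cdh1 (1.22 ± 0.219 to 0.666 ± 0.111 CPM) and Taf4b (21.4 ± 1.56 to 18.2 ± 0.620 CPM). Of 11 markers of differentiating spermatogonia, 3 fell and none rose (3 and 1 adjusted over the list alone), namely the cyclin gene Ccnd2 from 6.82 ± 0.853 to 3.50 ± 0.557 CPM, Uchl1 and Dmrt1. Calls were lost for Taf4b in 9, Dmrt1 in 8, Tspan8 in 7 and Uchl1 in 4 of 19 alternatives, mostly when 1 library was left out. Of 24 genes of the mitotic cell cycle, 4 fell and 2 rose (5 and 2 adjusted over the list alone). The checkpoint kinase gene Bub1b fell from 74.0 ± 1.37 to 59.3 ± 1.52 CPM and Ccna2 from 9.43 ± 0.710 to 6.80 ± 0.585 CPM, whereas the spindle motor Kif11 rose from 37.4 ± 1.06 to 51.2 ± 1.96 CPM. The mitotic list did not pass camera (adjusted p = 0.11) but passed fry.

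In the flagellum, Dnah8, a dynein heavy chain of the sperm tail, fell 1.54-fold from 1646 ± 122 to 1071 ± 93.0 CPM, Cfap61 1.36-fold and Cfap44 1.32-fold. Dnah8 lies among 4 genes that fell by at least 1 log2 unit, at 30.0 to 31.6 Mb of chromosome 17 in GRCm38. Ttc21a, an intraflagellar transport gene, rose from 267 ± 6.004 to 326 ± 16.1 CPM, and the axoneme list as a whole had 2 of 41 genes higher and 4 lower. Of 32 sperm surface, ADAM and fertilization genes, Adam6b rose and Adam1a and Plcz1, the phospholipase that activates the egg, fell (none of the 3 was called adjusted over the list alone). Their log2 fold changes were small, at -0.15 for Adam1a and -0.20 for Plcz1, and they were not called in 9 and 5 of 19 alternatives. Of 28 glycolysis entries, counted by identifier with Aldoa listed under 2, Tpi1 and Eno4 rose and Gpi1 fell, the latter not called in 5 of 19 alternatives. Eno4, a sperm enolase, went from 48.7 ± 2.84 to 67.8 ± 3.09 CPM. Of 12 multicopy genes of the Y and X chromosomes, 3 rose and none fell: Zfy2 from 7.48 ± 0.172 to 11.99 ± 2.25 CPM, Zfy1 and Fthl17a, while Spin2c stood at 0.775 ± 0.249 and 0.531 ± 0.142 CPM. Zfy1 was not called in 8 and Fthl17a in 5 of 19 alternatives, and read assignment among these gene copies is uncertain. None of the 15 germ cell and cell cycle lists passed camera, with adjusted p from 0.11 to 0.87.

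**Figure D4:**
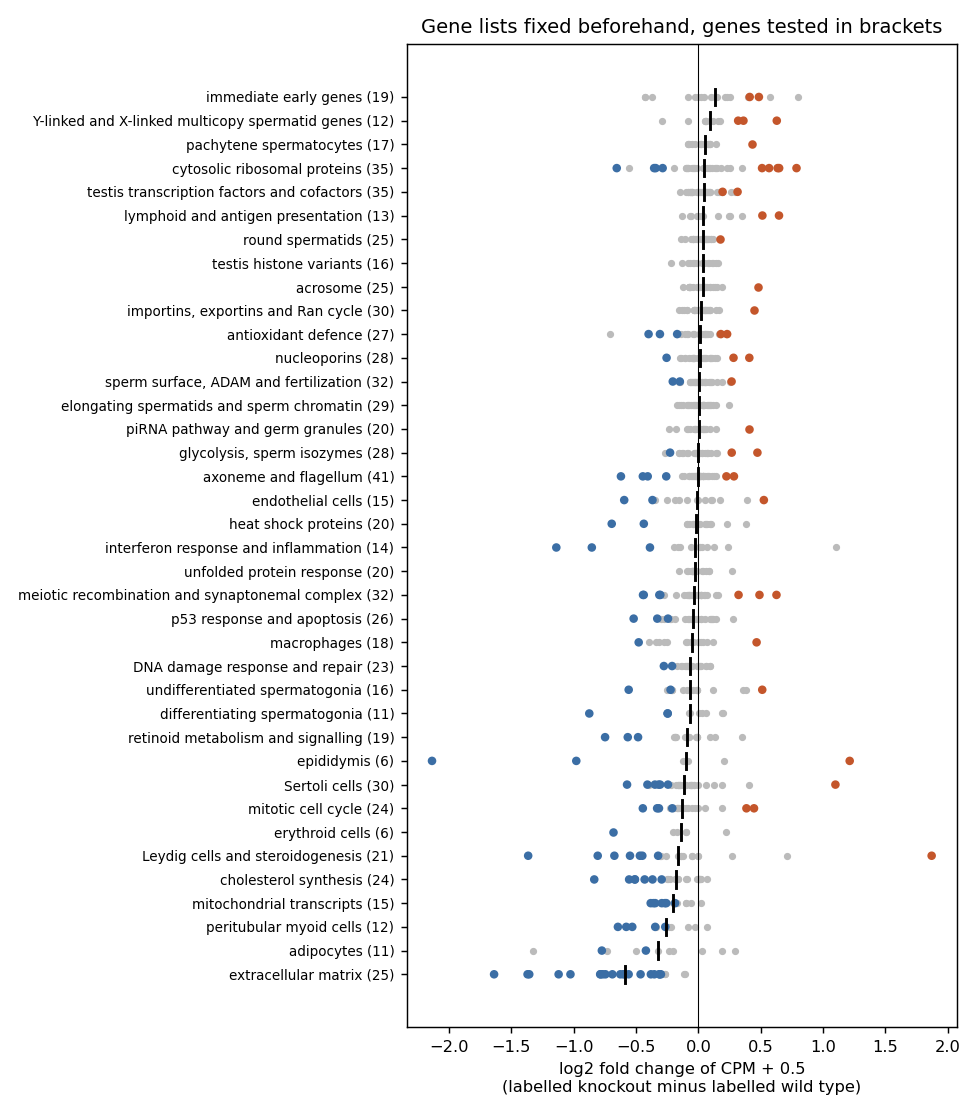
Log2 fold change of CPM + 0.5 (libraries labelled knockout minus libraries labelled wild type) of every tested member (points) of 38 gene lists fixed beforehand, with the median of each list (black bar) and coloured points for genes at an adjusted p under 0.05. The extracellular matrix list lies farthest from 0 with a median of -0.59, and the germ cell lists have medians between -0.13 and 0.09.

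Of 19 retinoid genes, limma called 3 lower and none higher, and DESeq2 3 lower and 1 higher. Aldh1a1, a retinaldehyde dehydrogenase, went from 292 ± 22.6 to 197 ± 15.1 CPM, Cyp26b1, which degrades retinoic acid, from 32.2 ± 2.91 to 22.9 ± 2.21 CPM and the receptor gene Rarb from 1.44 ± 0.179 to 0.669 ± 0.233 CPM. Rarg went the other way, from 4.65 ± 0.409 to 6.09 ± 0.978 CPM, without passing limma (adjusted p = 0.066) but passing in 3 of 19 alternatives, DESeq2 among them. Of 14 interferon and inflammation genes, limma called 3 lower and none higher, and edgeR and DESeq2 each called 3 lower and 1 higher. The falls were Stat2 from 15.6 ± 0.847 to 6.81 ± 0.700 CPM, Mx1 from 3.55 ± 0.494 to 1.77 ± 0.453 CPM and Nfkbia from 13.5 ± 1.43 to 10.1 ± 0.285 CPM. Saa3, an acute phase gene, stood at 0.338 ± 0.165 and 2.07 ± 2.74 CPM, the latter owing to 6.14 CPM in replicate 4. It was not called by limma (adjusted p = 0.13) but was called higher by edgeR and DESeq2 and without knockout replicate 1. The interferon list did not pass camera (adjusted p = 0.39) but passed fry. Of 26 genes of the p53 response and apoptosis, Cdkn1a, Pmaip1 and Casp9 fell and none rose (2 fell adjusted over the list alone), with Cdkn1a at 12.9 ± 0.617 and 10.2 ± 0.936 CPM, and Casp9 was not called in 12 of 19 alternatives. Of 27 antioxidant genes, 2 rose, Sod1 among them (146 ± 4.77 to 166 ± 10.9 CPM), and 3 fell, among them Gpx1 (31.2 ± 2.60 to 23.8 ± 3.91 CPM) and Sod2 (101 ± 4.91 to 89.97 ± 2.79 CPM). Sod1, Sod2 and Gpx1 were not called in 9, 8 and 3 of 19 alternatives, and the list's median of 0.02 had the other sign than its mean of -0.03. The unfolded protein response had no called gene among 20, by limma, edgeR or DESeq2, and 1 at an unadjusted p under 0.05. Of 20 heat shock genes 2 fell, of 23 DNA damage genes 2 fell (none adjusted over the list alone), and of 19 immediate early genes 2 rose. Of 35 cytosolic ribosomal proteins, 5 rose and 4 fell (5 and 5 adjusted over the list alone). Rplp0 rose from 222 ± 13.9 to 349 ± 25.5 CPM, Rps2 from 35.6 ± 0.836 to 53.1 ± 2.74 CPM and Rpsa from 18.96 ± 1.1195 to 29.8 ± 2.36 CPM, while Rps6 fell from 4.16 ± 0.563 to 2.47 ± 0.495 CPM. Ribosomal protein genes have many processed copies, and their levels are uncertain.

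Other lists held markers of tissues or of blood that a dissection can bring along. Of 6 measured epididymis genes, Spink8 fell from 4.998 ± 1.02 to 0.752 ± 0.240 CPM and Ros1 from 3.70 ± 0.586 to 1.75 ± 0.884 CPM, and Rnase10 rose from 1.96 ± 0.174 to 5.23 ± 0.617 CPM (2 rose and 2 fell adjusted over the list alone). The mean of this list relative to the wild-type label was -0.36 to -0.27 in the libraries labelled knockout and -0.16 to 0.13 in those labelled wild type. This lower mean rests on Spink8, with a log2 fold change of -2.14, while the median of the 6 genes was -0.10. It is therefore no measure of the amount of epididymis. Of 11 adipocyte genes 2 fell, of 6 erythroid genes 1 fell and of 13 lymphoid and antigen presentation genes 2 rose. The 13 lists of this paragraph and the preceding one had camera adjusted p between 0.24 and 0.89.

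Sequence that stays linked to a targeted gene can differ from that of control mice, so the surroundings of Kpna2 were examined. Within 10 Mb on either side of Kpna2, 60 of 381 tested genes were called (15.7%), against 3657 of 21581 elsewhere (16.9%). Fisher's exact test, two-sided, gave p = 0.58. Of the 396 genes with a position that changed by at least 1 log2 unit, 2.02% lay within 20 Mb of Kpna2. They were spread over all chromosomes, with 59 on chromosome 7 (3.47% of its tested genes), 34 on chromosome 14 (3.64%) and 32 on chromosome 6 (2.97%). The run with the most genes, in which consecutive large changes lie at most 1 Mb apart, covered 37.7 to 39.8 Mb of chromosome 7 in GRCm38. There 21 of 35 tested genes rose by at least 1 log2 unit, Pop4 among them and most others being predicted genes. Of the 396 genes, 50% had another within 1 Mb, against a median of 38.9% in random draws of tested genes, and 10 runs of at least 5 genes held 90 of them. Such runs held Dynlt1b with Tmem181b-ps on chromosome 17, Ndufaf3 with Spink8 on chromosome 9, Klk1b21 with Syt3 and, in another run, Fxyd5 on chromosome 7, and C1rb on chromosome 6. Called genes with smaller changes also lay within the span of such runs, Bub1b on chromosome 2 and Tpi1 on chromosome 6. Dnah8 on chromosome 17 and Gpi1 on chromosome 7 lay within shorter runs, and Gpx1 lay within 1 Mb of Ndufaf3. Whether these genes changed with their surroundings or with their lists was not tested.

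**Figure D5:**
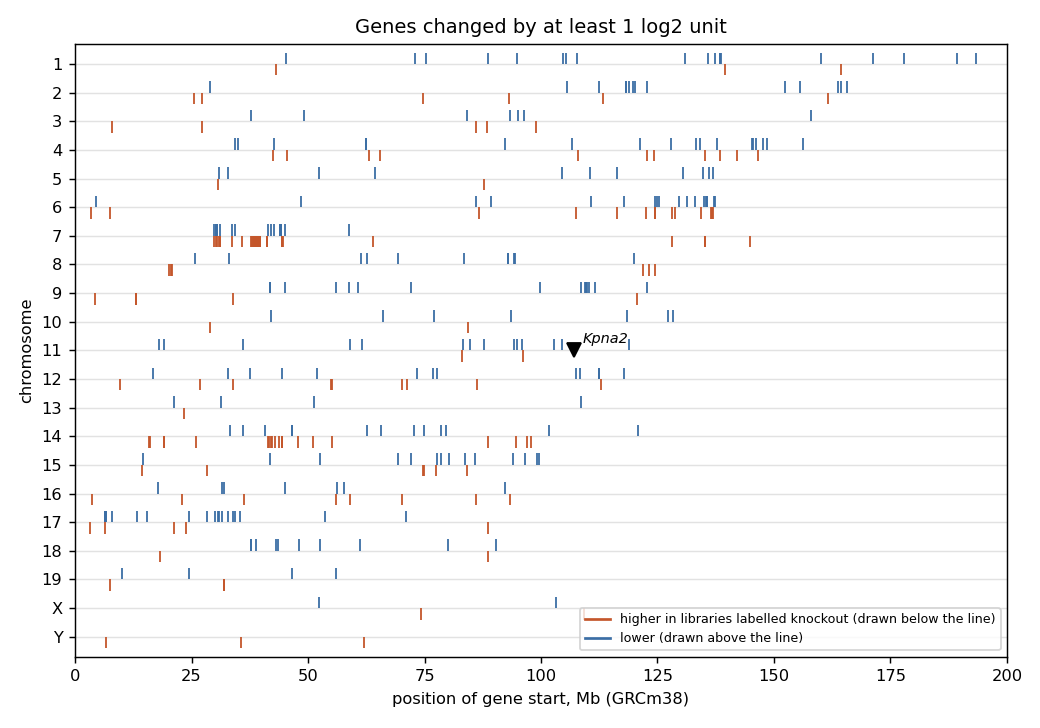
Position of the start of each gene changed by at least 1 log2 unit (Mb in GRCm38) on 21 chromosomes, with genes higher in the libraries labelled knockout drawn below each line and lower genes above it, and Kpna2 marked on chromosome 11. Chromosome 7 holds 59 of them (3.47% of its tested genes) and chromosome 14 holds 34 (3.64%), and 2.02% of the large changes lie within 20 Mb of Kpna2.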

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

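The comparisons of single libraries with the rest of their group were made for all named genes, all tested lists, the reads per library and the share of mitochondrial genes, and the remarks on neighbouring genes were chosen after the values were seen. In 24 of 296 groups of 4 libraries, 1 library stood far from the other 3 by Dixon's criterion, where chance gives about 14.8.

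Some cases lay in genes that also differed between the groups. Dynlt1b had 19.2 CPM in knockout replicate 1 and at most 1.57 CPM in the other libraries labelled knockout, and its neighbour on chromosome 17, Tmem181b-ps, 7.06 CPM against at most 1.00 CPM. Wild-type replicate 2 had 18.1 CPM of Pop4, where the others of its group had at most 9.12 CPM, and 18.7 CPM of Lpo, where they had at most 8.65 CPM. Syt3 stood at 19.1 CPM in knockout replicate 3 against at most 11.3 CPM, and Klk1b21 at 1.69 CPM in knockout replicate 4 against at most 1.08 CPM. Saa3, which was not called by limma but was by edgeR and DESeq2, stood at 6.14 CPM in knockout replicate 4 against at most 1.20 CPM.

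Among lists, given as the mean log2 value relative to the wild-type label, the extracellular matrix genes of knockout replicate 4 stood at -0.92, with the other 3 between -0.57 and -0.52. The immediate early genes stood at 1.06 in knockout replicate 3 and at 0.29 in wild-type replicate 1, where the rest of either group lay below 0. Knockout replicate 1 was apart for undifferentiated spermatogonia with 0.14. Wild-type replicate 3 was apart for peritubular myoid cells with -0.19 and for lymphoid genes with -0.17, wild-type replicate 2 for interferon and inflammation genes with -0.10 and wild-type replicate 1 for testis histone variants with -0.035.

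Further departures were those of wild-type replicate 3 for Rae1 (56.2 CPM), Gpi1 (287 CPM) and Sod1 (139 CPM), and of wild-type replicate 4 for Vwf (18.7 CPM) and Cdh1 (1.55 CPM). Rps2 was apart in wild-type replicate 1 (36.9 CPM) and in knockout replicate 1 (57.2 CPM), Rpsa in knockout replicate 1 (26.3 CPM) and Ipo7 in knockout replicate 3 (42.9 CPM).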

How the results depend on the processing

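The setting that leaves out genes near strongly changed ones was added after the data were seen. Kpna2 was higher in the libraries labelled knockout in all 19 alternatives, with log2 fold changes of 0.38 to 0.55 and adjusted p of 3.1e-04 to 0.028. Without each library in turn, the genes called higher were 1448 to 1804, those called lower 1343 to 1768 and genes changed by more than 1 log2 unit 382 to 411. The last count was 645 with a pseudocount of 0.1 CPM, 149 with 2 CPM and 258 with a filter at a mean of 2 CPM, since a larger pseudocount shrinks the change of low genes and the stricter filter tests fewer of them. It was 732 with edgeR and 724 with DESeq2, whose fold changes carry less or no shrinkage by a pseudocount. Without the 6659 genes within 1 Mb of another gene changed by at least 1 log2 unit, 1196 genes were higher and 1134 lower, with fewer genes tested, and 15.2% of the remaining 15368 genes were called against 21.04% of those left out. The share of called genes around Kpna2 did not differ past the threshold from that elsewhere with windows of 5 Mb (13.7%, lower) or 20 Mb (18.3%, higher).

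The count of shifted lists was 0 with an estimated correlation, 3 with fry (extracellular matrix, mitotic cell cycle and interferon response) and 3 without the genes near strongly changed ones, and 2 to 7 without each library in turn, with 2 without knockout replicate 1 and 3 without wild-type replicate 4. The extracellular matrix list passed in 21 of 22 alternatives, the peritubular myoid list in 20, mitochondrial transcripts in 19, cholesterol synthesis in 17 and Sertoli cells in 10, and Leydig cells passed in 5. The cause of these changes was not tested. No list and no named gene passed the threshold in the opposite direction, but some that did not pass changed sign, such as Kpna6 with quantile normalization and the immediate early genes, whose median was -0.22 without knockout replicate 3. Of 107 named genes besides Kpna2, 82 kept their side of the threshold in every alternative that tested them.

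The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.031 to 0.039, and 1 of 8 libraries correlated best with its own number. With the replicate block, 1768 genes were higher and 1678 lower, genes changed by more than 1 log2 unit were 412, 6 lists were shifted and Kpna2 kept its change (adjusted p = 0.0090). In the simulation 53.7% of planted 1.5-fold changes were called, so genes not called may include changes of that size. Far fewer genes changed there than the 3731 called in the data, which makes the adjusted threshold stricter. The simulated share therefore does not give the share missed here.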

Other observations

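The tests of linked sequence, of Kpna2 background and exchanged labels, of the share of all somatic cells, of the sex chromosomes and the correlations among named protein-coding neighbours were chosen after the results were seen. The predictions of the others were written before their own results were seen. Those on gene copies, genetic background, fibroblasts and GC content nevertheless address patterns already found in these data, and none of these others was part of the first plan.

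Called genes of the sex chromosomes were mostly higher in the libraries labelled knockout. On the X chromosome 115 genes were higher and 34 lower, so that 77.2% of its calls were higher against 49.5% on the autosomes (Fisher's exact test, two-sided, p = 1.4e-11, over genes, which are not independent). On the Y chromosome 25 were higher and 5 lower. X-linked examples, chosen after their values were seen, were Sh3kbp1, an adaptor of receptor endocytosis, at 43.7 ± 1.86 and 72.4 ± 6.37 CPM, Rp2 at 40.4 ± 1.02 and 58.6 ± 3.75 CPM, and Vsig1 at 94.2 ± 3.54 and 131 ± 10.5 CPM (libraries labelled wild type and knockout, n = 4 each). The median of all 857 X-linked genes was only 0.05 above that of autosomal genes on the log2 scale (0.05 with median ratio scaling and 0.06 with quantile normalization), and 12 of the 35 splits of the libraries gave a difference as large. It was 0.08 and 0.11 in knockout replicates 1 and 2, but -0.0022 and -6.9e-04 in replicates 3 and 4, inside the range of -0.01 to 0.02 under the wild-type label. For 568 named protein-coding X-linked genes the difference was 0.0027, although 71 of them were called higher and 24 lower. For the 100 Y-linked genes, many of them copies with uncertain read assignment, the difference was 0.20, the highest of the other 34 splits being 0.17, and in knockout replicates 1 to 4 it was 0.19, 0.39, 0.03 and 0.08, of which that of replicate 3 lay inside the range of -0.09 to 0.04 under the wild-type label. Without knockout replicate 2 the Y-linked difference was 0.10.

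The 4 against 4 split given by the labels was compared with the other splits of the 8 libraries. Of 35 splits, 1, the real one, gave as many genes in each direction (1898 higher and 1833 lower; at most 1 in any other split) and as many genes changed by at least 1 log2 unit (398; 0 in any other). For these 3 counts the real split was the most extreme, and 1 of 35 is the smallest share that this comparison can give. Every other split mixes the 2 groups, which adds their difference to the spread on each side. The comparison therefore cannot exclude chance assignment of libraries. For the count of lists the real split was not extreme, as 20 of 35 splits gave at least the real 5, with up to 11. For the extracellular matrix list alone the real split gave the smallest camera p (1.3e-12; the smallest of the others was 8.1e-11), which was so in 1 of 35 splits. For peritubular myoid cells 4, for cholesterol synthesis 9, for Sertoli cells 10 and for mitochondrial transcripts 11 of the 35 splits gave a p as small.

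Kpna2 was not lower in the libraries labelled knockout. If the labels are right, a background of pseudogene reads that is equal in both groups, over a lost transcript, would leave a lower level under the knockout label. Kpna2 was higher there (limma adjusted p = 0.0079), which argues against such a background under that condition. A background that differs between the groups was not tested. An exchange of the 2 labels cannot be told apart from a knockout allele that keeps its transcript: the libraries labelled wild type have the lower level, at 72.4% of the other, which is no loss, and the effect of the allele on the transcript is not known from values per gene. An altered transcript under the knockout label may also account for the level, and this was not tested.

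Genes changed by at least 1 log2 unit lay close together: of 396 with a position, 50% had another within 1 Mb, against a median of 38.9% and an upper bound of the central 95% of 44.7% in 1000 random draws. Sequence linked to Kpna2 is argued against, with 2.02% of these genes within 20 Mb of it. For 181 named protein-coding genes, only neighbours with another symbol stem were counted, the stem being the part before the first digit or hyphen. This separates gene families only roughly. The share was 31.5%, below the same bound of 32.6% though above the median of 24.3%, so that reads shared between near-identical copies, or copy number, remain a candidate explanation. A genetic background that differs between the groups and segregates within them is a further hypothesis. Among the 500 genes that varied most within groups, neighbours 50 kb to 1 Mb apart deviated in the same libraries (mean correlation 0.39, with a 95th percentile of 0.045 for shuffled positions). The mean correlation was 0.24 over the 244 pairs with different symbol stems. For 61 such pairs of named protein-coding genes the mean size of the correlation was 0.63 against a 95th percentile of 0.45, with a signed mean of -0.17. These pairs thus stood out only by size, a measure chosen after the results were seen, and not by the predicted positive sign. Part of the large changes, and of smaller ones near them, may reflect strain differences and not the loss of Kpna2. This design cannot separate the 2, since strains are not given in the labels.

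Extracellular matrix genes were lower in the libraries labelled knockout. A fall of all somatic cells by as much as the matrix genes is argued against by 33 endothelial and macrophage genes. Their median was -0.04 against -0.59, and the permutation p of the difference, over genes that are not independent, was 1e-05, the smallest that 100000 resamples can give. The matrix list was singled out for its low values, and the endothelial and macrophage lists were chosen after the results were seen. This p is therefore no independent support, and only the medians are read here. Other somatic lists leaned lower, with medians of -0.12 (Sertoli cells), -0.16 (Leydig cells), -0.26 (peritubular myoid cells), -0.33 (adipocytes) and -0.14 (erythroid cells), against 0.04 for lymphoid genes. A smaller share of some somatic cells is therefore not excluded. A bias by GC content or transcript length is argued against as well, since the median was -0.57 after removal of that trend, with 20 of 25 genes called lower. Fewer fibroblasts or cells of the testis covering remain open: 22 measured fibroblast and mesothelial markers had a median of -0.15 (bootstrap 95% interval -0.53 to -0.07), with 8 lower and 1 higher. That interval holds both no more than a slight fall and one near that of the matrix genes. It came from resampling the markers, which are not independent, and does not measure the spread between libraries. The most abundant of these markers, Muc16, which was higher, and Cd34, which was lower, had means of 34.5 and 10.8 CPM, and a lower matrix output per cell, a biological explanation, was not tested, nor was a difference in tissue carried along at dissection.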
